A study of Mus musculus with 11 samples.

How the data were processed

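Gene expression was measured in hypothalamus and cerebellum of female laboratory mice aged 10 weeks. Per the labels' design text, 6 mice lost access to food at the start of the dark phase, 16 hours before tissue was taken, while 6 mice kept their chow. RNA of the 6 mice was pooled for each feeding state and region, which gave 4 pools. Each pool was hybridised 3 times to CodeLink whole genome arrays, single-colour arrays read through biotin-labelled cRNA and streptavidin Cy5, and 1 array of the fasted cerebellum was discarded after quality control. The 11 arrays comprise 3 of the hypothalamus of fed mice, 3 of the hypothalamus of fasted mice, 3 of the cerebellum of fed mice and 2 of the cerebellum of fasted mice. Arrays of a group are repeats of the same pooled RNA. Their spread holds labelling and hybridisation error and no difference between mice, so p-values with arrays as units compare pools and not feeding states.

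The deposited values are ratios. For each of the 34999 probes the median of the 3 fed arrays of a region was 1 (tolerance 1e-06), in hypothalamus and in cerebellum alike, so the authors had divided each probe by the fed median of its own region. The lowest deposited ratio was 0.01 and no value was missing. Software, background correction and scaling between arrays are not given in the sources used here, and that the ratios are linear was judged from the values. Signal intensities are not kept in such ratios, so probes near background could not be recognised by their level. No level can be compared between probes or between regions. The comparison of hypothalamus with cerebellum levels that had been planned was therefore not made. A difference of log2 ratios between fasted and fed arrays of a region, and the difference of that change between regions, are unaffected by the division.

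Each array was divided by its median ratio, values under 0.1 were set to 0.1, and log2 was taken. limma 3.58.1 in R 4.3.3 fitted the 4 group means over all 11 arrays, with 7 residual degrees of freedom and 1.82 prior degrees of freedom, and gave two-sided moderated tests with Benjamini-Hochberg adjustment over 34999 probes. A probe was called at an adjusted p under 0.05, and calls of at least 1.5-fold were also counted. The variance prior had been planned with a trend on intensity. Because the mean log2 ratio is no intensity, the prior without trend became the reported fit and the prior with trend an alternative. For the same reason a gene with several probes is represented by the probe with the smallest residual SD between arrays, where the brightest probe had been planned, and where no list member was called the 2 with the smallest residual SD are given.

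Genes were named from the platform annotation. Of the probes, 21590 had 1 gene symbol, 681 had several and were not used to name a gene, and 12728 had none here. The named probes cover 18048 genes, 2998 of them with over 1 probe, and 21462 of the named probes matched the RefSeq gene table of assembly GRCm38.p6 by Entrez identifier, which changed 0 symbols. No coordinates are given because the build behind the probes is not stated.

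Before the data were examined, 42 gene lists were fixed for pathways, cell types and neighbouring tissues, together with the rule for genes named in the text. For fasting in each region the rule takes the 10 genes higher and the 10 genes lower with the largest change among called genes with 1 symbol, a higher group mean above the median of all probes, and no overlap between the arrays of the groups. For the difference between regions it takes 5 each way. It adds up to 4 called members per list, Npy, Pomc, Cartpt, Xist and Y-linked genes. No probe with 1 symbol named Agrp. The filter on the group mean assumed intensities and marks no brightness on ratios. Among lower genes it passes those whose fed mean lay above the median of all probes, so larger falls can be left out. Diaph3, called at -1.89 in hypothalamus, was left out of the lower genes this way. The 41 lists with 3 or more measured members were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, each adjusted over the 41 lists. The list test of the difference between regions was added after seeing the data.

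The steps were tested on simulated log2 ratios drawn with the residual SDs of the real probes, extremes trimmed, with 50 probes changed at each fold size among 34999. For fasting in hypothalamus, 64% of probes changed 1.5-fold and 84% of those changed 2-fold were recovered, against 14% at 1.2-fold. For fasting in cerebellum the shares were 56%, 86% and 10%, and for the difference between regions 46%, 78% and 0%. Unchanged probes made up 2.27%, 4.76% and 1.85% of the calls. Far fewer probes changed in the simulation than were called in the data, 14.2% in hypothalamus and 20.9% in cerebellum. The adjustment depends on that share, so the simulated shares need not hold for the reported fit. The number of arrays limits the precision. Replicate numbers were checked for pairing by the Spearman correlation of deviations from the group means. For fed and fasted hypothalamus the 3 same-number correlations lay between 0.116 and 0.187, and those of different numbers between -0.154 and -0.0212. Deviations from a group mean sum to 0, so same-number correlations above 0 pull the others below 0. With 3 arrays per group few matchings exist, so a pairing of these arrays is possible but not shown. For cerebellum the 2 correlations were -0.0736 and 0.0508, but the 2 fasted arrays deviate by equal and opposite amounts, so this check is weak. Between fed arrays of both regions they were 0.0179, 0.151 and 0.18 for numbers 1, 2 and 3. Between fasted hypothalamus and fed cerebellum they were 0.0081, 0.173 and 0.241, against at most 0.118 for any arrays of different number. A tie of numbers 2 and 3 across regions therefore stays open. The reported fit and the simulation have no block. For the fit, the group means without a block were planned beforehand, but not the prior without trend or the choice of probe. The alternatives were quantile normalization, 75th percentile scaling, other floors, an offset, a variance trend, array weights, fits of fewer groups, a replicate block, each array left out, pools as units, stricter thresholds and other choices of probes. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.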

Results

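Transcripts of the hypothalamus, which holds the circuits of appetite, and of the cerebellum were compared between mice fasted for 16 hours and mice fed ad libitum, to find which genes change with fasting in each region and whether the change differs between them. The values are ratios to the fed median of the region. Changes are given as log2 fasted minus fed ± SE of the limma fit, from 2 arrays of the fasted cerebellum and 3 of each other pool. The median SD between arrays of a pool lay between 0.06 and 0.09 log2. Arrays repeat 1 pool of 6 mice, so the tests show differences between pools.

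In the fasted hypothalamus, the hormone gene Prl (prolactin) was 3.60 ± 0.06 log2 higher, or 12.1-fold, on 3 of 3 arrays (adjusted p = 5.06e-08). Plin4, which encodes a lipid droplet protein, was 1.45 ± 0.08 higher, and Sult1a1, a sulfotransferase gene, 1.04 ± 0.07 higher. Pcp2 of Purkinje cells rose by 1.54 ± 0.11, Fat2 of granule cells by 1.36 ± 0.08 and Cbln3 of granule cells by 0.76 ± 0.05. Neurod1 of granule cells (0.51 ± 0.05) and Car8 of Purkinje cells (0.59 ± 0.06) also rose. The lists they belong to went both ways, with 3 higher and 5 lower of 22 granule cell genes (adjusted p = 0.849, camera) and 2 higher and 3 lower of 20 Purkinje cell genes (adjusted p = 0.463). Other probes of Cbln3 and Plin4 rose by 1.88 and 0.69, and other probes of Fat2 (-0.20) and Car8 (0.09) were not called. Mybpc3, which encodes a myosin-binding protein, rose by 1.12 ± 0.12. Of the genes lower in the fasted pool, Pou4f1, a transcription factor gene of the habenula, stood at -2.01 ± 0.39, Rhbdf1 at -1.92 ± 0.31, 1700095A13Rik at -1.87 ± 0.34 and Trim61 at -1.59 ± 0.16.

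**Figure D1:**
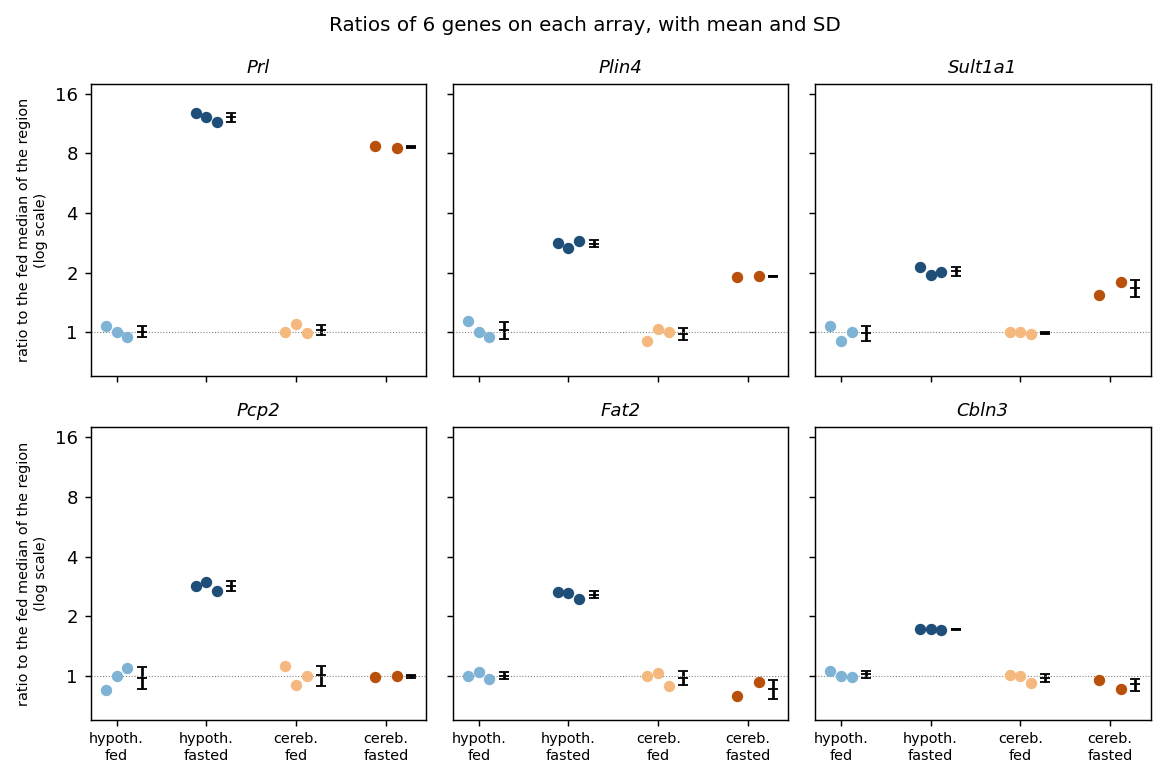
Ratio of each array to the fed median of its region (vertical, log scale) for 6 genes in the 4 pools (horizontal). Points are arrays and bars the mean with SD. The fasted hypothalamus arrays lie above the fed arrays for each gene, and Prl, Plin4 and Sult1a1 are also higher on both fasted cerebellum arrays.

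Otud4 (8.82 ± 2.28) and Ftdc1 (7.05 ± 2.01) varied widely within a pool, and their 3 fed arrays spanned ratios from 0.995 to 419 and from 0.995 to 128. Both probes had the same ratios on fed replicates 1 and 3, 1 and 0.995305. Separate signals would hardly give this, so their denominators are doubtful and the sizes of these 2 changes carry no meaning. Snora47 and 2310026I22Rik were higher by 1.47 ± 0.35 and 0.94 ± 0.20. Gm12709, 1700052I22Rik, Upk3b, Gm10747 and 1700109H08Rik were lower, between -2.33 and -1.49, as was Map7d3, whose size is set by the floor of 0.1 because 1 fasted array lay under it. With the floor at 0.01, Map7d3 (adjusted p = 0.0635) and Ftdc1 (0.0819) were not called. These 10 of the 20 genes named by rule each lost the call without at least 1 array, and the other 10 kept it without any 1 of the 11 arrays. Under all alternatives with arrays as units only 3 of the 20 kept it, Prl, Sult1a1 and Trim61. The filter on extreme ratios removed the Prl probe, so Prl was not tested there. With pools as units, run only for the average over both regions, 0 probes were called. Mybpc3, Pou4f1, Rhbdf1 and 1700095A13Rik lost the call with quantile normalization over all arrays and within regions, and Pcp2 and Fat2 within regions.

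Arcuate peptide genes, which regulate feeding, passed no test in the hypothalamus. Npy stood at 0.03, Pomc at 0.06 ± 0.05 and Cartpt at -0.07 ± 0.06, and 0 of 5 measured members were called. Among 26 other neuropeptide and hormone genes 2 were called, Cck (-0.75 ± 0.11) and Vgf (-0.44 ± 0.05), both lower. With the replicate block in hypothalamus arrays alone their adjusted p was 0.0742 and 0.0751. Other Vgf probes, at -0.27 and 0.07, were not called.

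Of 26 glucocorticoid-induced genes in the hypothalamus, 5 rose, 1 fell and 20 were not called (6 and 1 adjusted over the list alone). Besides Plin4 and Sult1a1, Hif3a rose by 0.40 ± 0.05, while Klf9 stood at -0.30 ± 0.05. Other probes of Hif3a (0.19 and 0.03) and Klf9 (-0.20) were not called. Camera gave an adjusted p = 0.0165, and adjusted p = 0.552 with an estimated correlation. Without replicate 1 of the fasted hypothalamus the camera adjusted p was 0.0557. Of the 11 measured pituitary genes, Prl, Ghrhr (0.32 ± 0.07) and Tbx19 (0.26 ± 0.07) rose, Tshb stood at -0.31 ± 0.07 and 7 were not called, with 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.0135, camera; adjusted p = 0.346 with an estimated correlation; 0.0668 with a variance trend).

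Of 70 respiratory chain subunits in the hypothalamus 13 fell and 0 rose (16 and 0 adjusted over the list alone), with Cox6b1 at -0.47 ± 0.09, Atp5k at -0.35 ± 0.05 and Uqcrc1 at -0.34 ± 0.04 (adjusted p = 7.03e-05, camera; adjusted p = 0.493 with an estimated correlation). Of 19 cholesterol synthesis genes 6 fell and 0 rose (8 and 0 adjusted over the list alone), among them Insig1 (-0.44 ± 0.09), Ebp (-0.33 ± 0.06) and Cyp51 (-0.30 ± 0.04). Of 19 heat shock chaperones 6 fell and 0 rose (8 and 1 adjusted over the list alone), led by Cryab (-0.57 ± 0.14) and Chordc1 (-0.56 ± 0.05). Camera gave adjusted p = 0.0102 for each, and adjusted p = 0.552 with an estimated correlation.

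Markers of cell types and of neighbouring tissue moved in the same comparison. Of 14 thalamus markers 9 fell and 0 rose (12 and 0 adjusted over the list alone), with Prkcd at -0.78 ± 0.06, Synpo2 at -0.74 ± 0.06, Tcf7l2 at -0.69 ± 0.05 and Plekhg1 at -0.47 ± 0.05 (adjusted p = 7.08e-08, camera; adjusted p = 0.346 with an estimated correlation). Other probes of Prkcd (-0.12) and Synpo2 (-0.12 and 0.00) were not called. Oligodendrocyte genes fell in 7 of 18 cases, with Ugt8a at -0.63 ± 0.07 and Olig1 at -0.56 ± 0.07, and microglia genes in 6 of 15, with Fcer1g at -0.32 ± 0.07. Pan-neuronal genes fell in 4 of 19 cases, with Nefm at -0.51 ± 0.06. For these the camera adjusted p was 0.0042, 0.0102 and 0.0112, with 0 members called higher, and 9, 9 and 7 members were lower adjusted over the list alone, against 0, 1 and 1 higher. Each had adjusted p = 0.493 with an estimated correlation. Genes of pericytes and meninges were higher in 9 of 17 cases, with Ogn at 0.49 ± 0.05 and Col1a2 at 0.35 ± 0.07, and 9 higher and 1 lower adjusted over the list alone (adjusted p = 0.00606, camera; adjusted p = 0.536 with an estimated correlation).

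In all, 4980 of 34999 probes were called in the hypothalamus, 2220 higher and 2760 lower (44.6% higher), and 443 of these changed at least 1.5-fold, 61 higher and 382 lower. The count was 2442 without fed replicate 1, 2165 without fed replicate 2, 2329 without fasted replicate 2 and 1940 without fasted replicate 3 of the hypothalamus. With the replicate number as a block it was 5458 in the fit of all arrays, where Otud4 (adjusted p = 0.0528), Gm12709 (0.05001) and Eif2s3y (0.0542) were not called. In the hypothalamus arrays alone the block gave 48 by limma, against 2210 without it. Of the 133 genes named for hypothalamus or for the difference between regions and called in hypothalamus as reported, 122 were called with the block in the fit of all arrays. In the hypothalamus arrays alone 76 were called without the block, and with it 5, Prl, Fat2, Sult1a1, Trim61 and Slc17a7. The other 128, which include Plin4, Prkcd and Synpo2 (0.0501 each), Cbln3 (0.0511), Pcp2 (0.0562) and Tcf7l2 (0.0661), had an adjusted p from 0.0501 to 0.179 there, while the same 10 lists were called. The balance of directions depends on the scaling. With quantile normalization, which forces the narrow spread of fed arrays and the wide spread of fasted arrays on one another, 33 were called over all arrays (66.7% higher) and 19 within regions (47.4% higher), and with 75th percentile scaling 9254 (7.72% higher).

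In the fasted cerebellum, Prl was 3.07 ± 0.07 log2 higher (adjusted p = 5.43e-07), or 8.39-fold, on 2 of 2 arrays, Plin4 0.96 ± 0.09 and Sult1a1 0.74 ± 0.08 higher. Pomc, the precursor of melanocortins, was 1.32 ± 0.05 higher and Cartpt stood at -0.60 ± 0.07, while Npy (-0.24) was not called. The genes Hacd3 (-1.64 ± 0.06), Kcnd3 (-1.59 ± 0.06) and Sgpp1 (-1.44 ± 0.05) fell. Kcnd3 encodes a potassium channel and Sgpp1 a sphingosine-phosphate phosphatase. Another Kcnd3 probe, at -0.06, was not called. Apoa4 (-2.71 ± 0.35), Clec4d (-2.44 ± 0.35) and Gal (-1.61 ± 0.33) also fell, and Chn1os3 rose by 2.03 ± 0.36. Of the 20 genes named by rule, Prl, Hacd3, Kcnd3, Sgpp1, Apoa4, Clec4d, Gal and Chn1os3 kept their call without any 1 of the 11 arrays, and the rest did not. Under all alternatives with arrays as units 4 of the 20 kept it, Prl, Hacd3, Kcnd3 and Sgpp1, though the filter on extreme ratios removed the Prl probe. Apoa4, Gal and Chn1os3 lost the call with quantile normalization over all arrays and within regions. Gal also lost it in the fit of only the groups compared, and Clec4d with a variance trend. Cfap43, Krt6b, 4933421I07Rik, Ifna6, Hba-x, 2410017I17Rik and Diaph3 were higher, between 8.89 ± 2.41 and 2.02 ± 0.49, and Gm10747 lower (-1.78 ± 0.50). 6430562O15Rik was higher and Apobec4, 4933411K16Rik and Lhfpl1 lower, each with 1 cerebellum array under the floor of 0.1, which sets the size of their change. With the floor at 0.01, 6430562O15Rik (adjusted p = 0.0829), Lhfpl1 (0.0758) and Cfap43 (0.0576) were not called.

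Genes of endoplasmic reticulum stress were lower in the fasted cerebellum. Of 18 members 11 fell and 0 rose (11 and 0 adjusted over the list alone), with the chaperone genes Hyou1 at -1.34 ± 0.09, Canx at -1.26 ± 0.06 and Hspa5 at -0.84 ± 0.09 and with Pdia4 at -0.82 ± 0.06 (adjusted p = 0.000322, camera; adjusted p = 0.336 with an estimated correlation). Another Canx probe, at -0.13, was not called. Of 16 fatty acid synthesis genes 9 fell and 0 rose (10 and 1 adjusted over the list alone), among them Fasn, fatty acid synthase (-1.39 ± 0.08), Fads2 (-0.67 ± 0.05) and Srebf1 (-0.63 ± 0.05), with adjusted p = 0.00171 (camera) and adjusted p = 0.336 with an estimated correlation. Other probes of Fasn (-0.11), Fads2 (-0.17) and Srebf1 (-0.65) were not called.

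Of 26 glucocorticoid-induced genes 10 rose, 2 fell and 14 were not called in the cerebellum (10 and 3 adjusted over the list alone), with Map3k6 at 0.68 ± 0.05 and Cdkn1a at 0.59 ± 0.07 beside Plin4 and Sult1a1 (adjusted p = 0.00645, camera; adjusted p = 0.538 with an estimated correlation; 0.0663 with the first probe of each gene). Of 60 ribosomal protein genes 6 rose and 0 fell (4 and 0 adjusted over the list alone), with Rplp1 at 0.50 ± 0.08 and Rpl3l at 0.49 ± 0.10 (adjusted p = 0.00645, camera; adjusted p = 0.336 with an estimated correlation). Of 19 heat shock chaperones 7 fell and 0 rose (9 and 0 adjusted over the list alone), led by Hsph1 (-0.82 ± 0.13) and Hspa4l (-0.65 ± 0.08), with adjusted p = 0.026 (camera), 0.638 with an estimated correlation, 0.0764 without fed replicate 2 and 0.0803 without fasted replicate 2 of the cerebellum, and 0.0622 and 0.0647 with quantile normalization over all arrays and within regions. Choroid plexus genes, a tissue beside the cerebellum, fell in 6 of 13 cases (6 adjusted over the list alone), led by Kl (-0.65 ± 0.07), with adjusted p = 0.0197 (camera), 0.538 with an estimated correlation, 0.0606 without fasted replicate 1, and 0.0813 and 0.092 with the same quantile settings. The pituitary list, with Prl and Ghrhr (0.44 ± 0.07) higher, had adjusted p = 0.0669 (camera) and 0.336 with an estimated correlation. It passed at 0.0478 without fed replicate 3, 0.0413 without fasted replicate 2 of the cerebellum, 0.0282 with 75th percentile scaling and 0.0461 with all probes of each gene.

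Glial, neuronal and clock genes of the cerebellum went both ways. Of 15 astrocyte genes 2 rose and 5 fell (2 and 6 adjusted over the list alone), with Gja1 at -0.95 ± 0.06, Slc1a3 at -0.62 ± 0.08 and Agt at 0.45 ± 0.10. Of 18 oligodendrocyte genes 1 rose and 7 fell (1 and 7), with Aspa at 0.36 ± 0.08 and Ugt8a at -0.82 ± 0.08. Of 19 pan-neuronal genes 4 rose and 3 fell (4 and 3), with Elavl3 at 0.32 ± 0.07 and Syt1 at -1.27 ± 0.06. Of 18 clock genes 1 rose and 5 fell (1 and 5), with Per3 at 0.93 ± 0.04 (other probes at 0.33, called, and -0.34, not called) and Nr1d2 at -0.81 ± 0.11. Camera called none of these 4 lists (adjusted p = 0.259, 0.684, 0.832 and 0.184). Fry, which tests whether the genes of a list move on balance one way and sets them against no other genes, gave adjusted p = 0.00264, 0.019, 0.0436 and 0.0106. Over the 41 lists fry called 22 in hypothalamus, 28 in cerebellum and 9 for the difference between regions, among them the 10, 6 and 5 that camera called, and its test for changes in either direction 39, 39 and 40. In all, 7302 probes were called in the cerebellum, 3382 higher and 3920 lower (46.3% higher), and 1535 changed at least 1.5-fold, 705 higher and 830 lower. The count was 4540 without fasted replicate 1, 411 with quantile normalization over all arrays (16.8% higher), 480 within regions (33.3% higher) and 11088 with 75th percentile scaling (15.6% higher).

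**Figure D2:**
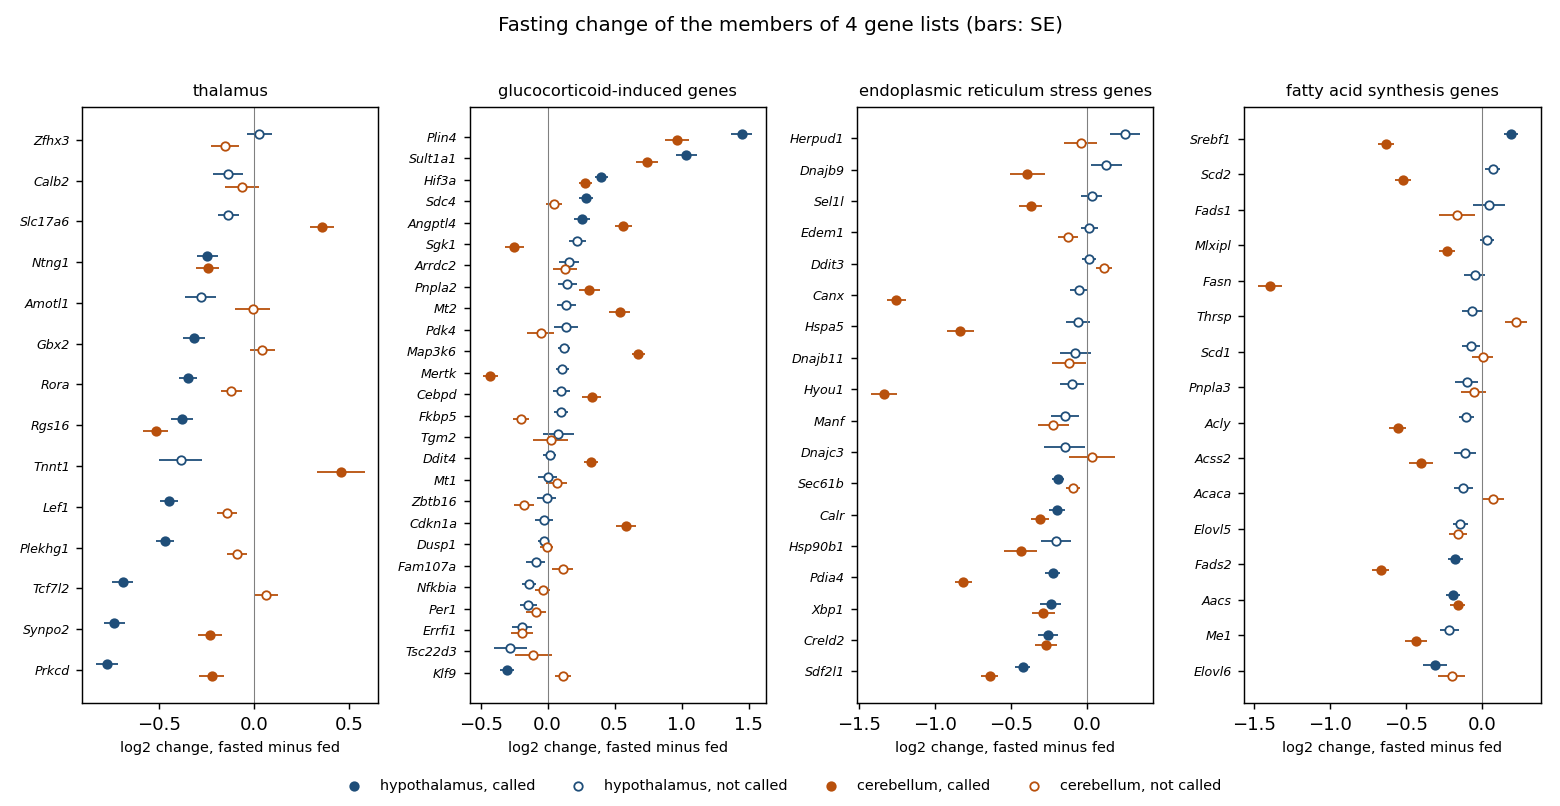
Log2 change, fasted minus fed (horizontal), for each measured member of 4 gene lists (vertical) in hypothalamus and cerebellum. Points are estimates, bars the SE, and filled points passed the test over all probes. Hyou1, Canx and Fasn lie far below 0 in cerebellum and near 0 in hypothalamus.

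The fasting change differed between regions for 6184 probes by the interaction test of limma, with 3032 changes more positive and 3152 more negative in hypothalamus. The count was 117 with quantile normalization over all arrays and 119 within regions. Ogn, a proteoglycan gene of meninges, differed by 1.87 ± 0.08 log2 (adjusted p = 3.27e-05), at 0.49 ± 0.05 in hypothalamus and -1.38 ± 0.06 in cerebellum. Slc30a5, a zinc transporter gene, differed by 1.84, Itih2 by 1.76, Hoxa5 by 1.48 and Pdcd6ip by 1.42. In the other direction Diaph3 differed by -3.90 and 1700095A13Rik by -3.70, and both kept the call without any 1 array, as did 4930573C15Rik (-3.77). Krt6b (-4.56) and 1700027F06Rik did not. For 1700027F06Rik, 2 arrays lay under the floor of 0.1, which sets its size, and with the floor at 0.01 its adjusted p was 0.14 (limma). Diaph3, 1700095A13Rik, 4930573C15Rik, Krt6b, 1700027F06Rik and Pdcd6ip lost the call with quantile normalization over all arrays and within regions. Ogn, Slc30a5, Itih2 and Hoxa5 kept it under all alternatives with arrays as units. Among lists, endoplasmic reticulum stress genes (adjusted p = 0.0308) and genes of pericytes and meninges (0.00337) were lower in cerebellum relative to hypothalamus. Respiratory chain subunits (0.000173), ribosomal proteins (0.013) and thalamus markers (0.000406) were lower in hypothalamus relative to cerebellum, by camera on the interaction. With an estimated correlation the adjusted p was 0.848, 0.773, 0.715, 0.715 and 0.715. The endoplasmic reticulum list missed the threshold without fasted hypothalamus replicate 1 (0.0593), fed cerebellum replicate 2 (0.0597) or fasted cerebellum replicate 2 (0.0507), and the ribosomal list with quantile normalization over all arrays (0.0851) and within regions (0.0971).

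Calls shared by both regions were counted. Both regions came from the same mice, so a shared call is no independent repeat of the feeding effect. Higher in both regions were 369 probes, against 214.5 for independent lists, and lower in both 564 against 309.1. Higher in hypothalamus and lower in cerebellum were 222 against 248.6, and the reverse held for 458 against 266.7. The ratios were 1.72 and 1.82 for the same direction and 0.89 and 1.72 for opposite directions. Both tests share the residual SD of a probe, so probes with little spread are called in both regions more often than independent lists assume. The excess therefore does not by itself show a shared response. The same-direction total of 933 was 555 and 448 without fed replicates 1 and 2 and 474 and 418 without fasted replicates 2 and 3 of the hypothalamus, and 574 without fed and 550 without fasted replicate 1 of the cerebellum. It was 287 in fits of only the groups compared, 1530 with array weights, 2 with either quantile normalization and 3555 with 75th percentile scaling. Across probes, which are not independent replicates, the changes had a Spearman correlation of 0.056. Of 66 probes called at 1.5-fold or more in both regions, 14 rose in both, 23 fell in both and 29 went opposite ways. Prl, Plin4 and Sult1a1 rose in both, and Fabp7 (-0.65 ± 0.07 in hypothalamus, -0.66 ± 0.08 in cerebellum) and Ugt8a fell in both, while Diaph3 and 1700095A13Rik were lower in hypothalamus and higher in cerebellum. Averaged over regions, 7956 probes were called with arrays as units. With the 4 pool means as units, which leaves 1 residual degree of freedom, 0 probes were called by limma, 1306 had an unadjusted p under 0.05, and Prl ranked 2 of all probes at 3.33 ± 0.17 (adjusted p = 0.889). The pools of both regions in a feeding state share their mice, so these 4 units are not independent for feeding.

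Control genes were set beside these calls. Female mice carry no Y-linked genes, of which 6 had a probe. Yet Eif2s3y (-0.21 ± 0.05) and Zfy1 (0.15 ± 0.04) were called in hypothalamus and Sry (-0.50 ± 0.05) in cerebellum. Uty, Kdm5d and Zfy2 were called in neither region. Whether these probes bind other transcripts was not checked, so the calls need not come from background. Xist stood at 0.00 in hypothalamus and -0.49 ± 0.07 in cerebellum, where another probe, at 0.29, was not called. Of genes with 2 or more called probes, 29 of 122 in hypothalamus and 92 of 288 in cerebellum had probes called in opposite directions.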

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

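The tests on Prl and on cerebellar genes were chosen after the results were seen. Those on the second thalamus list and on probe pairs were prompted by patterns already seen, but set before their own values were seen. The fasting change differed between regions, by the interaction test of limma, for 6184 probes (117 and 119 with quantile normalization over all arrays and within regions), for 26 of the 45 genes named by rule and for 137 of 222 further genes named as list examples. These genes were picked for a large change in a region or by this same test. Their shares therefore do not show how common a difference is, which was 17.7% over all probes. Differences are hypothalamus change minus cerebellum change, log2. They were positive for Apoa4 (3.14), Ogn (1.87), Slc30a5 (1.84), Itih2 (1.76), Clec4d (1.68), Gal (1.67), Pcp2 (1.55), Hacd3 (1.54), Fat2 (1.54), Hoxa5 (1.48), Pdcd6ip (1.42), Kcnd3 (1.41), Sgpp1 (1.39), Mybpc3 (1.06), Prl (0.53) and Plin4 (0.49). They were negative for 1700027F06Rik (-4.81, a size set by the floor of 0.1), Krt6b (-4.56), Diaph3 (-3.90), 4930573C15Rik (-3.77), 1700095A13Rik (-3.70), Pou4f1 (-3.04), 1700052I22Rik (-2.80), Gm12709 (-2.79), Chn1os3 (-1.75) and Trim61 (-1.48). The lists that differed had a camera adjusted p of 0.0308 (endoplasmic reticulum stress), 0.000173 (respiratory chain), 0.013 (ribosomal proteins), 0.00337 (pericytes and meninges) and 0.000406 (thalamus), and with an estimated correlation an adjusted p of 0.848, 0.715, 0.715, 0.773 and 0.715, which ends each call.

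Prl was higher in both fasted pools, and an unstable ratio from a denominator near 0 is argued against by the residual SD of its probe, at the 37.7th percentile of all probes. Pituitary tissue or RNA in the fasted pools stays open: without Prl, the 10 other measured pituitary genes had a median change of 0.12 in hypothalamus, at percentile 97.6 of 10000 random lists, and 0.08 in cerebellum, at percentile 91.7, while Tshb fell in hypothalamus, and the ratios do not show how many of these genes either tissue expresses. The test lacks Gh, an abundant pituitary transcript, which had only a probe with several symbols that was not used. Pomc, a gene that pituitary and hypothalamus both express, rose in cerebellum. A change of Prl with fasting in the tissue itself was not tested and stays open, with 1 pool per group.

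Region markers moved in the fasted hypothalamus pool, with Cbln3, Fat2 and Pcp2 higher and thalamus markers lower. Cerebellar tissue in that pool stays open. Of 17 other genes listed as cerebellar, 3 were called higher, among them Car8 (0.59 ± 0.06) and Neurod1 (0.51 ± 0.05). Another 4 were called lower, among them En1 (-0.81 ± 0.06, chosen after its value was seen) and Grid2ip (-0.49 ± 0.06). The median of the 17, 0.00 (SD 0.35), at percentile 62.4 of random lists, decides nothing over members that go both ways. Whether hypothalamus or neighbouring tissue expresses the 17 genes was not checked, so their falls do not argue against cerebellar tissue. A second thalamus list of 24 genes had a median of -0.20, at percentile 0 of 10000 random lists, with 10 called lower and 0 higher. Less thalamic tissue in the fasted hypothalamus pieces may therefore account for part of the calls, as a hypothesis, and Cbln3, Fat2 and Pcp2 stay unexplained. A change of these genes with fasting was not tested apart from dissection.

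Some probes of 1 gene disagreed about the fasting change in cerebellum. Over 2998 genes the changes of 2 probes had a Spearman correlation of 0.154 in cerebellum and 0.132 in hypothalamus, and the difference of 0.0216 had a 95% bootstrap interval from -0.0282 to 0.0728. Wrong annotation or different transcripts, which act in both alike, would give such likeness, and so would noise around 0 in unchanged genes. The low values therefore do not decide between these. An effect on single probes of the fasted cerebellum arrays cannot be told apart from them at this interval. Probes near background could give the same low values, and the ratios do not show which these are. Where both probes were called, 79.2% of 96 pairs in hypothalamus and 71.1% of 239 pairs in cerebellum had the same direction.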

How the results depend on the processing

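The prior without trend, the robust prior, the floor of 0.01, the filter on extreme ratios, the first probe of each gene, the block in hypothalamus arrays alone, the result averaged over regions, its alternatives and the list result for the difference between regions were chosen after seeing the data, as was 75th percentile scaling for all results but that difference. The planned filter on dim probes and the comparison of levels between regions were not run, because ratios hold no brightness, and for the same reason signal over background cannot be given. No named gene or list that was called, as reported or in the alternative, changed direction between them. Sign changes of genes and lists called in neither were not counted. The balance of hypothalamus calls turned from mostly lower to mostly higher under the first setting. Quantile normalization over all arrays gave 33 called probes in hypothalamus (66.7% higher), 411 in cerebellum (16.8%), 117 for the difference between regions, 187 averaged over regions and 2 in the same direction in both. Within each region it gave 19 (47.4%), 480 (33.3%), 119, 141 and 2. Its construction shows the cause: the interquartile range of fed arrays, 0.016 to 0.099 log2, is narrow because they set the denominator, against 0.245 to 0.311 in fasted arrays. By the same construction, 75th percentile scaling moved the median of all probes to -0.11 in hypothalamus and -0.12 in cerebellum and gave 9254 calls (7.72% higher), 11088 (15.6%), 13768 averaged and 3555 shared, against 44.6% and 46.3% higher as reported. Calls of at least 1.5-fold numbered 443, 1535, 2064, 358 and 37 in the order of the first setting, and an adjusted p under 0.01 gave 1162, 3945, 2855, 3523 and 193. A fit of only the groups compared gave 2210 in hypothalamus and 287 shared, and array weights 8971 and 1530; the cause was not tested. With pools as units 0 probes were called. Leaving out 1 array gave 1940 to 5438 calls in hypothalamus, 4540 to 7549 in cerebellum, 4351 to 6307 for the difference, 5466 to 8125 averaged and 418 to 992 shared, and 9 to 11, 5 to 8 and 4 to 5 lists. With an estimated correlation 0 lists were called in hypothalamus (10 as reported), 0 in cerebellum (6) and 0 for the difference (5). Where 1 fasted cerebellum array was left, it was assumed to vary like the other groups. Replicate numbers may pair the hypothalamus arrays, and a tie of numbers 2 and 3 across regions stays open. Over all groups 7 of 15 same-number correlations were over 0.1, against 2 of 30 for different numbers. Of the 11 arrays, 8 correlated best with their own number. A replicate block gave 5458, 7320, 5934, 8754 and 1089 probes, called the same 10 lists in hypothalamus, and in cerebellum added pericytes and meninges (adjusted p = 0.0378) and pituitary (0.0378). Within hypothalamus arrays alone it gave 48 probes and 10 lists; this fit has fewer arrays and few residual degrees of freedom. Without fed cerebellum replicate 3, pericytes and meninges passed in cerebellum (0.0478), and without fed hypothalamus replicate 1, endoplasmic reticulum stress in hypothalamus (0.0454). Over all alternatives of single lists, 2908 values kept their side of the threshold, 36 lost the call and 8 gained it. For named genes these counts were 6138, 1780 and 19.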

Other observations

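The count of probes without a gene symbol was made only after the results were seen. Immediate early genes were not called as a list by camera in hypothalamus (adjusted p = 0.659) or in cerebellum (0.892), while fry, which sets a list against no other genes, gave 0.122 and 0.0382. In hypothalamus 4 of 22 were called lower and 0 higher, with Arc at -0.33 ± 0.09 and Jun at -0.31 ± 0.05. In cerebellum 4 were lower and 2 higher, with Junb at 0.45 ± 0.06, Dusp6 at -0.86 ± 0.08, Egr1 at -0.70 ± 0.07 and Nr4a3 at -0.69 ± 0.05, another probe of which, at 0.05, was not called. In the list of cortex and hippocampus 3 of 16 genes were lower in the fasted hypothalamus (adjusted p = 0.196, camera; 0.0028, fry), with Slc17a7 at -0.84 ± 0.06 and Nrgn at -0.60 ± 0.07, and the dopamine transporter gene Slc6a3 stood at -0.62 ± 0.05. Ttr, an abundant choroid plexus gene, stood at -0.81 ± 0.06 there. In cerebellum the ketone and lactate transporter gene Slc16a1 stood at -0.95 ± 0.05 and Sqle of cholesterol synthesis at -1.12 ± 0.09, while Angptl4 rose by 0.57 ± 0.06.

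Probes without a gene symbol lay above probes with 1 symbol in the cerebellum, at a median change of 0.05 against -0.02. Because each array was divided by its overall median, only this relative difference is shown, and the signs depend on the scaling. With 75th percentile scaling the medians were -0.08 and -0.15, and 1093 unnamed probes were called higher and 2198 lower, against 614 and 6992. As reported, among unnamed probes 1887 were called higher and 630 lower, and among probes with 1 symbol 1446 higher and 3239 lower. In hypothalamus the counts were 961 and 775 against 1218 and 1933. With 75th percentile scaling they were 307 and 2303 against 393 and 6090 there, so the direction of unnamed probes turned.

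The real split of the 6 hypothalamus arrays called 4980 probes and 10 lists. Of the 10 splits, 1 (the real one) reached these values, and the highest of the others called 1 probe and 2 lists. With 10 splits a share under 0.05 is out of reach. Every other split mixes arrays of the fed and the fasted pool. Any difference between these pools, whatever its source, would make the real split stand out, so the splits cannot tell feeding from it. Of the 4 splits that part all 3 same-number pairs, as the real one does, the others called at most 0 probes and 1 list, and the 6 that part 1 pair at most 1 probe and 2 lists.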
